A study of Mus musculus with 16 samples.

How the data were processed

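RNA was measured in cardiac tissue of 16 C57BL/6J mice with Illumina bead arrays, 1 array per mouse. Per the labels, 8 mice carried an AKIP1 overexpression transgene and 8 were wild type, and within each genotype 4 mice had ischemia/reperfusion (I/R) injury and 4 had a sham operation. Total RNA was isolated with TriReagent, its quality was checked on an Experion instrument, and biotinylated cRNA was made with the Illumina TotalPrep kit, per the labels' protocols. The arrays lay on 2 slides of 8, and each slide held 2 arrays of every group, per the labels. The timing of tissue collection, the part of the heart taken and the numbers of probes removed before deposition are not given in the sources used here.

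The deposited values are probe intensities on a linear scale, 25697 probes on each of 16 arrays, with no detection p-values. The authors' software, background correction and normalization are not given in the sources used here. In the deposited intensities, the sorted values of the arrays differed by at most 7.53% at any rank (median 0.109%), so that the distributions had already been equalised between arrays. The lowest intensity was 162 and the array medians lay between 178.8 and 178.9, so that a background level or an added offset was still in the values. The mean intensity of 65.6% of the probes lay no more than 10% above the median. Changes of such dim probes are understated or lost. Because the distributions were equalised, a change of total RNA per heart cannot be seen, and each change is relative to the rest of the array.

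The files do not pair probe IDs with genes, and 0 Illumina IDs were found in the RefSeq gene table used here. Probes are therefore given by ID. The plan fixed before the data were examined called for 1 value per gene, gene lists for heart and I/R injury, and Akip1 in every comparison. None of these could be computed, and each probe was tested by itself instead. The plan would have named up to 10 genes per direction by the size of change among those past the threshold whose groups did not overlap (for the interaction and the mean of both surgeries, past the threshold only), and, where fewer than 5 passed, also those with the smallest p. This was kept with at most 2 probes per direction in each comparison, taken first by the size of change and then by p, so that not every called probe is named. Probes taken by p entered the checks of named probes but are not printed for that comparison, except ILMN_2729762 after I/R. ILMN_2729762 and ILMN_1215469, named after sham, are followed in other comparisons whether or not named there.

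Intensities were background-corrected with the normexp method (offset 50), not normalized again, and log2 transformed, the treatment planned for values found to be linear. Linear models with 4 group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes). The 6 comparisons were I/R against sham within each genotype, transgenic against wild type within each operation, the genotype by surgery interaction, and the transgenic effect averaged over both operations. P-values were adjusted by Benjamini-Hochberg over 25697 probes within a comparison, with a threshold of 0.05. Counts at an unadjusted p under 0.05 are also given. With no difference at all, about 0.05 of the 25697 probes would fall there. All adjusted p-values are limma's, and SE is the moderated standard error of the log2 difference.

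An I/R response score was computed per array from the probes past the threshold for the I/R effect averaged over both genotypes. It is the mean over these probes of the log2 value minus the mean of the 8 sham arrays, with the sign of the averaged effect. Genotypes were compared by a two-sided exact permutation test over 70 assignments, whose smallest possible p is 0.0286. Since the arrays also chose the probes, the score was used to compare genotypes and not to test I/R itself. Overlap of calls between genotypes was set against n1 × n2 / N for independent lists. Each genotype had its own sham arrays, but both lists came from the same fit with a shared estimate of spread per probe.

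The limma step was tested on simulated data with 200 of 25697 probes changed in the wild-type I/R comparison. It recovered 82.5% of changes of 0.5 log2, 97% of changes of 1 log2 and 100% of changes of 2 log2, with 6, 12 and 6 false calls. Changes were added after background correction to probes drawn at random, with independent normal noise and no deviant array. The simulation therefore checks the fit, and its recovery does not give the sensitivity for real changes, which are compressed in dim probes. For the I/R response score, a simulated ratio of 0.7 between genotypes came back as 0.708. Precision is limited by 4 arrays per group. The median SE of a difference between 2 groups was 0.056 log2 over all probes, most of which were dim. For the probes named in the comparisons of I/R against sham, the SE was 0.21 to 0.82 log2.

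Alternatives planned before the data were examined were slide as a block, each slide alone, only probes above the median mean brightness, cyclic loess in place of the deposited normalization, fits with only the groups compared, array weights, and leaving out each array in turn. Log2 intensities without background correction, and fits without the array labelled WT_IR replicate 2 with slide as a block, were added after seeing the data. Replicates are numbered within a group and do not pair mice. Figures were drawn with matplotlib 3.10.9.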

Results

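Transcripts were measured in hearts of wild-type mice (WT) and of mice overexpressing AKIP1 (TG), a protein that binds protein kinase A, after I/R or sham surgery. I/R interrupts blood flow to heart muscle and then restores it, whereas the sham operation serves as its control. The study asked whether AKIP1 overexpression changes I/R injury. Each of the 4 groups held 4 mice, with 1 array per mouse and 25697 probes per array. Median deposited intensities were 178.8 to 178.9 on all 16 arrays. Arrays of the same group correlated across probes with Pearson's r between 0.963 and 0.995, and probes are not independent replicates. The AKIP1 transgene itself could not be followed, because the files do not pair probes with genes.

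Surgery was the main difference between the arrays. The first principal component held 65.7% of the variance and the second 7.34%. On the first component, 7 of the I/R arrays lay apart from the 8 sham arrays, while the array labelled WT_IR replicate 2 lay among the sham arrays. The I/R response score, taken over 5897 probes (2743 higher and 3154 lower after I/R), was 0.0372 on that array. It was 0.538, 0.514 and 0.325 on WT_IR replicates 1, 3 and 4. Scores of the 8 sham arrays ranged from −0.0571 to 0.0485. Its label was kept, and the count of called probes in each comparison is also given without it, a choice made after seeing the data.

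**Figure D1:**
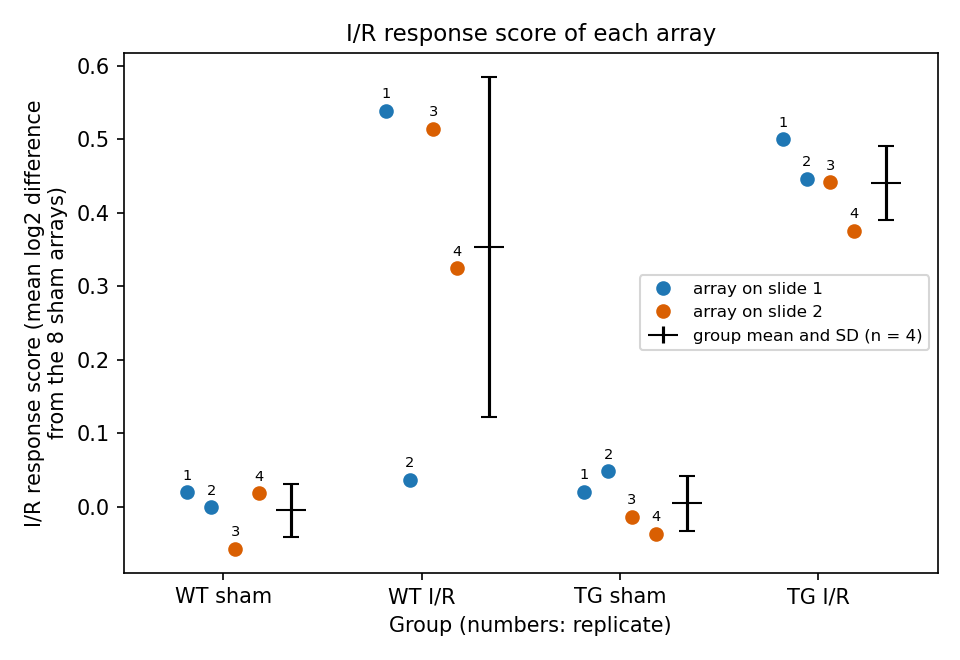
I/R response score (mean log2 difference from the 8 sham arrays, signed by the direction of the I/R effect) for each array in the 4 groups, with points for arrays coloured by slide, numbers for replicates, and bars for the group mean and SD (n = 4). Of the I/R arrays, 7 lie between 0.325 and 0.538, and WT_IR replicate 2, at 0.0372, lies within the range of the sham arrays.

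In wild-type hearts, I/R changed 1865 of 25697 probes (7.26%), with 915 higher and 950 lower. Among these, 126 rose and 21 fell by more than 2-fold. Probe ILMN_2759365 rose 6.03-fold (log2 difference 2.59, SE 0.34, adjusted p = 0.0093), from 7.55 ± 0.23 in sham to 10.14 ± 0.60 after I/R (log2 intensity, SD, n = 4 each). Probe ILMN_2713285 rose 4.63-fold (SE 0.31 log2, adjusted p = 0.0144). The strongest falls were those of ILMN_1241151 (log2 difference −2.05, SE 0.43, adjusted p = 0.0251), and ILMN_2593694 (log2 difference −1.79, SE 0.35, adjusted p = 0.0221). With all arrays, neither fall passed in transgenic hearts (adjusted p = 0.0877 and 0.104). Without WT_IR replicate 2, ILMN_1241151 passed there (adjusted p = 0.0453) and ILMN_2593694 did not. TG_Sham replicates 1 and 2 lay within the TG_IR range. For ILMN_1241151 they stood at 8.94 and 8.79 log2 (TG_IR 7.31 to 9.03, TG_Sham replicates 3 and 4 at 10.31 and 10.25). For ILMN_2593694 they stood at 7.86 and 7.83 (6.84 to 8.17, and 9.20 and 9.11). All 4 probes were named among calls whose 4 I/R arrays did not overlap the 4 sham arrays, which held for 1038 of the calls. Over all probes, called or not, the groups did not overlap in 8.11%, where chance gives 2.86%.

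Without the array labelled WT_IR replicate 2, 4829 probes changed in wild type, 2324 higher and 2505 lower, and these included 1856 of the 1865. More than 2-fold changes then numbered 314 higher and 96 lower. With that array kept, the count depended on each other wild-type array. It was 15 without WT_IR replicate 1, 6 without replicate 3 and 262 without replicate 4, and 611, 0, 16 and 34 without WT_Sham replicates 1, 2, 3 and 4, while leaving out TG_IR replicate 3 gave 1204. Only 12 probes passed when the fit held the wild-type arrays alone, and of the named probes ILMN_2713285, ILMN_1241151 and ILMN_2593694 did not. Of 25 alternatives, ILMN_2759365 lost its call in 2, ILMN_2713285 in 4, ILMN_1241151 in 8 and ILMN_2593694 in 7. With slide as a block the count was 1419, and within slides it was 0 on slide 1, which carries WT_IR replicate 2, and 2648 on slide 2 (2 arrays per group each).

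In transgenic hearts, I/R changed 3860 probes (15.0%), with 1901 higher and 1959 lower. More than 2-fold changes were seen for 271 probes that rose and 63 that fell, and 39 rose by more than 4-fold. ILMN_2952275 rose 17.1-fold (log2 difference 4.09, SE 0.82, adjusted p = 0.00615), from 7.35 ± 0.40 to 11.44 ± 0.34 (log2 intensity, SD, n = 4 each), and the log2 difference was 3.37 without background correction. ILMN_2710905 rose 15.5-fold (log2 difference 3.95, SE 0.73, adjusted p = 0.00477). In wild type, ILMN_2952275 rose 5.95-fold and ILMN_2710905 rose 6.13-fold with all arrays. Without WT_IR replicate 2, these wild-type rises were 12.6-fold and 12.1-fold. ILMN_1253966 fell by 1.72 log2 (SE 0.21, adjusted p = 0.00264) and ILMN_2906855 fell by 1.59 log2 (SE 0.28, adjusted p = 0.00451). Of the 3860 calls, 3559 had no overlap between the 4 I/R and the 4 sham arrays. Over all probes, called or not, 20.02% had none, where chance gives 2.86%. The count was 3637 with slide as a block, 0 on slide 1 alone and 2394 on slide 2 alone. It was 2473 without TG_IR replicate 1, 2508 without TG_Sham replicate 4 and 4912 (2353 higher and 2559 lower) without WT_IR replicate 2, which enters through the shared estimate of spread.

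The I/R responses of the genotypes ran in the same direction. Of the probes called, 761 were higher in both genotypes, where independent lists would share 67.7, and 679 were lower in both, where they would share 72.4. Because the lists share an estimate of spread and hold mostly bright probes, some overlap beyond these numbers would arise without a shared response. A single probe was called in opposite directions. Of the 3860 transgenic calls, 97.6% had the same sign in wild type. Log2 fold changes of the genotypes correlated with r = 0.908 across probes, which are not independent replicates. Without WT_IR replicate 2, 1863 probes were higher and 1860 lower in both (213 and 249 for independent lists), 2 were called in opposite directions, and r was 0.930.

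**Figure D2:**
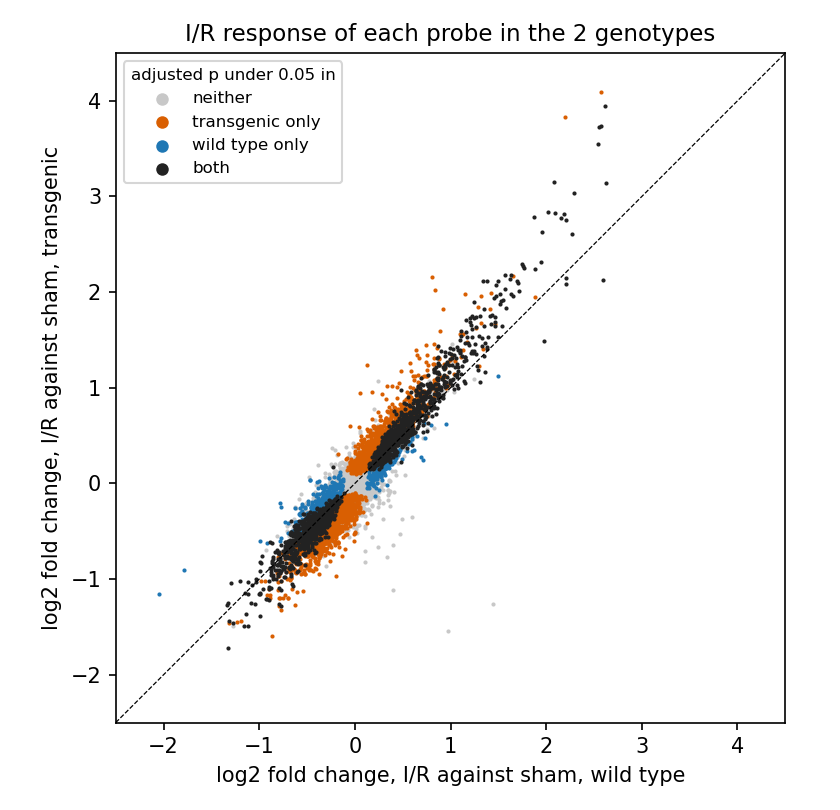
Log2 fold change of each of 25697 probes after I/R against sham in wild type (horizontal axis) and in transgenic hearts (vertical axis), coloured by the genotype in which limma's adjusted p was under 0.05, with a dashed line of equal change. The fold changes of the genotypes correlate with r = 0.908 in the fit with all 16 arrays, WT_IR replicate 2 included.

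No probe passed the test for a different I/R response between genotypes. limma's interaction term gave 0 probes with all arrays and 0 without WT_IR replicate 2, and 1067 and 1059 probes at an unadjusted p under 0.05. Both of these counts are below the share of 0.05 of the probes that no difference at all would give. The smallest adjusted p was 0.905 and 0.47. The response score was 0.441 ± 0.051 in TG_IR and 0.354 ± 0.232 in WT_IR (SD, n = 4 each). The difference of 0.0872 was within the spread between arrays (two-sided exact permutation p = 0.629, 95% interval −0.161 to 0.462). Without WT_IR replicate 2, the sign turned: the score was 0.406 ± 0.049 (n = 4) in TG_IR and 0.426 ± 0.110 (n = 3) in WT_IR, a difference of −0.0204 (two-sided exact permutation p = 0.743, interval −0.167 to 0.162). After sham, the score was 0.0048 ± 0.0375 in TG and −0.0048 ± 0.0361 in WT (SD, n = 4 each, two-sided exact permutation p = 0.743).

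After sham surgery, transgenic and wild-type hearts differed in 4 probes, 1 higher and 3 lower in transgenic. ILMN_2729762 was 46.7-fold higher (log2 difference 5.55, SE 0.50, adjusted p = 0.000314), at 12.61 ± 0.38 in TG_Sham against 7.07 ± 0.45 in WT_Sham (log2 intensity, SD, n = 4 each). Without background correction, the log2 difference was 4.66. Whether this probe detects the transgene is not given in the sources used here. ILMN_1215469 was 2.34-fold lower (log2 difference −1.23, SE 0.13, adjusted p = 0.00142), at 11.03 ± 0.34 in TG_Sham against 12.26 ± 0.02 in WT_Sham (SD, n = 4 each). For all 4 called probes, the arrays of the groups did not overlap. ILMN_2981550 was also lower (log2 difference −0.35, SE 0.05, adjusted p = 0.0357), but lost this call in 18 of 25 alternatives. At an unadjusted p under 0.05 there were 1535 probes, and 1758 without WT_IR replicate 2. No difference at all would give about 0.05 of the probes, which both counts exceed, and the excess was not tested.

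The calls of ILMN_2729762 and ILMN_1215469 were kept in 24 of 25 alternatives each, the exception being slide 1 alone (2 arrays per group), which gave 0 calls at log2 differences of 5.45 and −1.31, while slide 2 alone gave 2. Slide as a block gave 4 calls. The count was 6 without WT_IR replicate 2 and 2 without TG_IR replicate 1, TG_Sham replicate 1, 2 or 3, WT_IR replicate 1, 3 or 4, or any of the 4 WT_Sham arrays.

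After I/R, 0 probes differed between transgenic and wild-type hearts in limma's test. At an unadjusted p under 0.05 there were 1265, below the share of 0.05 of the probes that no difference would give. ILMN_2729762 stood at 11.36 ± 0.24 in TG_IR and 8.51 ± 1.43 in WT_IR (SD, n = 4 each; log2 difference 2.85, SE 0.50, adjusted p = 0.525). Its value was 10.59 on the array labelled WT_IR replicate 2, and 8.30, 7.45 and 7.70 on WT_IR replicates 1, 3 and 4. Without replicate 2, it was the 1 probe called, 11.7-fold higher in transgenic (log2 difference 3.54, SE 0.25, adjusted p = 1.62e-05), with 1064 probes at an unadjusted p under 0.05. ILMN_1215469 had a log2 difference of −0.58 (SE 0.13, adjusted p = 0.955) with all arrays and −0.58 (SE 0.14, adjusted p = 0.999) without replicate 2. Both probes were named from the sham arrays. Their unadjusted p after I/R in limma's test was 4.08e-05 for ILMN_2729762 and 0.000472 for ILMN_1215469. TG_IR arrays lay above every WT_IR array for ILMN_2729762 (at least 11.14). For ILMN_1215469 they lay below (11.42 to 11.82 against 12.01 to 12.36). Over all probes, 2.57% did not overlap, where chance gives 2.86%. The count of called probes was 0 with slide as a block, and 1 on slide 2 alone and with array weights.

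**Figure D3:**
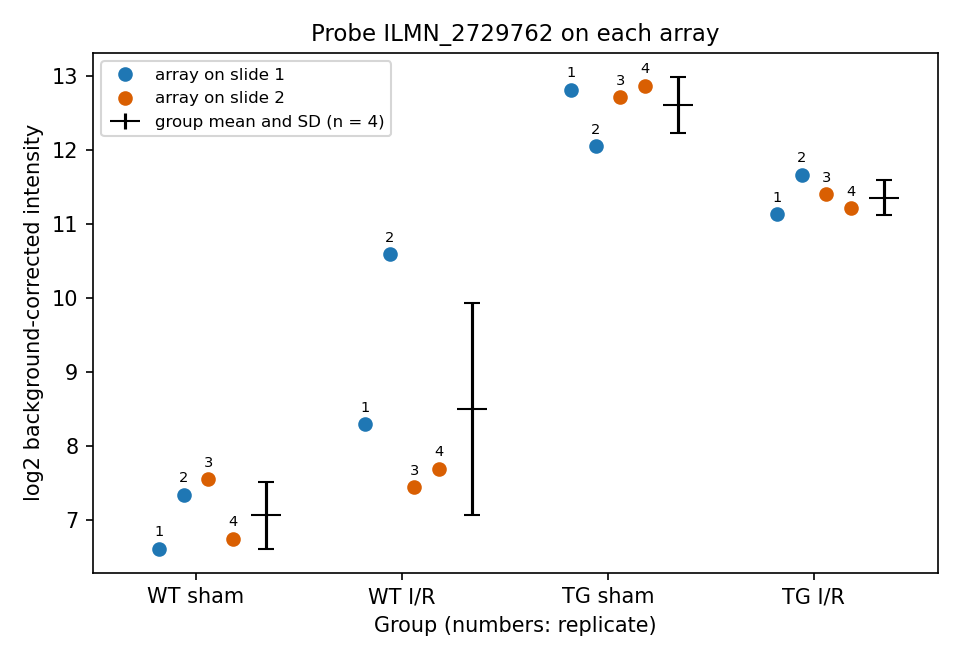
Log2 background-corrected intensity of probe ILMN_2729762 on each array in the 4 groups, with points for arrays coloured by slide, numbers for replicates, and bars for the group mean and SD (n = 4). Means are 12.61 in TG_Sham and 11.36 in TG_IR against 7.07 in WT_Sham, and WT_IR replicate 2, at 10.59, lies between the wild-type and transgenic arrays.

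The 2 probes with the largest genotype difference after sham were also compared between TG_Sham and TG_IR. Having been chosen on the TG_Sham arrays, they are favoured to lie closer to wild type in other arrays. ILMN_1215469 rose by 0.60 log2 from TG_Sham to TG_IR (SE 0.13, adjusted p = 0.00862), whereas its wild-type difference was −0.05 (SE 0.13, adjusted p = 0.89). ILMN_2729762 had a log2 difference of −1.26 from TG_Sham to TG_IR (SE 0.50, adjusted p = 0.109). Without WT_IR replicate 2, whose removal lowers the shared estimate of spread for this probe, the SE of that difference was 0.23 and the adjusted p was 0.00124. The interaction of neither probe passed: it was −2.70 log2 (SE 0.70) for ILMN_2729762 and 0.65 log2 (SE 0.18) for ILMN_1215469, each with an adjusted p of 0.999. Without WT_IR replicate 2, it was −2.003 log2 (SE 0.34, adjusted p = 0.47) for ILMN_2729762 and 0.65 log2 (SE 0.19, adjusted p = 1.00) for ILMN_1215469.

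Averaged over both operations, transgenic and wild-type hearts differed in 2 probes, with 1674 at an unadjusted p under 0.05 (1703 without WT_IR replicate 2). These 1674 and 1703 exceed a share of 0.05 of the probes, and the excess was not tested. ILMN_2729762 was 18.3-fold higher (SE 0.35 on the log2 scale, adjusted p = 0.000125), and its log2 difference without background correction was 3.54. ILMN_1215469 was 1.87-fold lower (log2 difference −0.90, SE 0.09, adjusted p = 0.000847). The count was 4 without WT_IR replicate 2, with slide as a block and with array weights. It was 0 on slide 1 alone and 2 on slide 2 alone.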

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

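Within each group of 4 arrays, the named probes and the I/R response score were searched for a single array far from the other 3, which chance gives in about 1 of 20 groups. In 80 such searches 2 were found, where chance would give 4. Both were on the array TG_IR replicate 2. The search flagged 0 values on WT_IR replicate 2, its response score included, so an array can depart without being flagged. ILMN_2952275 stood at 10.94 log2 there, against 11.56 to 11.66 on the other TG_IR arrays. ILMN_2710905 stood at 11.68 log2, against 12.91 to 12.96. Both probes were called as higher after I/R in transgenic hearts, and on this array too they lay above all TG_Sham arrays.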

How the results depend on the processing

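The settings without background correction and without WT_IR replicate 2 with slide as a block, and the overlap without WT_IR replicate 2, were chosen after seeing the data. The interaction gave 0 probes in each alternative it was run under, which leaves out the fits with only the groups compared. Cyclic loess kept every count within 1.5 times (WT I/R 1732, 54.6% higher against 49.1%; TG I/R 3793, 55.2% higher against 49.2%; TG against WT after sham 3, after I/R 0, mean of both surgeries 2), as did slide as a block except for 4 in the mean of both surgeries. Slide 1 alone gave 0 in I/R against sham in either genotype, in TG against WT after sham and in the mean. Slide 2 alone gave 2394 in TG I/R, 2 after sham and 1 after I/R. The probes brighter than the median gave 2 after sham and 2236 shared I/R calls, against 1440 over all probes. Fits with only the groups compared gave 12 in WT I/R (2 higher, 10 lower) and 2 after sham. Their fold changes were the same by construction, so that the estimate of spread made the difference. Array weights, which gave WT_IR replicate 2 a weight of 0.377, gave 3937 in WT I/R, 1 after I/R and 4 in the mean. Log2 values without background correction gave 983 in WT I/R, 43% of them higher. Where no construction is named, the cause was not tested.

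Leaving out each array in turn gave 0 to 4829 in WT I/R, 2473 to 4912 in TG I/R, 2 to 6 after sham, 0 to 1 after I/R, 0 to 0 for the interaction and 2 to 4 for the mean. The TG_IR minus WT_IR score ran from −0.0204 (without WT_IR replicate 2) to 0.158, with exact permutation p between 0.343 and 0.857. The sham score difference ran from −0.0073 (without TG_Sham replicate 2) to 0.0225, and was also below 0, at −0.00355, without WT_Sham replicate 3. Without WT_IR replicate 2 and with slide as a block, the counts were 4962 in WT I/R, 7 after sham, 1 after I/R and 4 in the mean, and the score difference was −0.0201. Without it, 3723 I/R calls were shared between genotypes. Besides the 2 turned sham score differences just given, values of named probes and of the sham score difference kept direction and side of the threshold in 529 cases, passed it newly in 8 and no longer passed it in 47. Of the WT and TG I/R calls, 97.9% and 97.2% were of probes brighter than the median, so that dim probes were little tested. Not run, because probes are not paired with genes, were the mean of all probes of a gene and the tests of gene lists. No paired analysis was possible because the labels number the mice singly and pair none across groups.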

Other observations

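The tests of an exchanged label, of a heart that did not respond and of transgenic RNA for WT_IR replicate 2, and both tests of the probe set of slide 1, were chosen after the result was seen.

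A set of 12 probes was more than 2-fold higher on both TG_Sham arrays of slide 1 than on those of slide 2, by 1.84 log2 on average, and was chosen for this. It stood at 9.09 and 9.17 log2 in TG_Sham replicates 1 and 2, 8.71 in TG_IR replicate 2 and 7.92 in WT_IR replicate 2, and at 6.93 to 7.68 on the other arrays, TG_IR replicate 1 on slide 1 (7.27) among them. An effect of slide 1 is argued against, since wild-type arrays of slide 1, without WT_IR replicate 2, differed from those of slide 2 by −0.388 log2. For this set, an effect of the transgene in all transgenic mice is argued against by I/R arrays, which did not choose the set. TG_IR replicates 1, 3 and 4 stood at 7.27, 7.66 and 7.60, and WT_IR replicates 1, 3 and 4 at 7.36, 7.68 and 7.59. On slide 1, TG_IR exceeded WT_IR replicate 1, the only WT_IR array left there, by 0.63 log2. This lay between the limits set for the test, which therefore cannot tell, and it rests on TG_IR replicate 2. An effect in only some transgenic mice stays open. The choice of the set kept out probes that were high in TG_Sham on both slides, so other probes are not covered. A difference between the mice or in the part of the heart taken was not tested.

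The array labelled WT_IR replicate 2 resembled a sham array, and an exchange of its label with one of the series is argued against, since 0 of the 8 sham arrays reached the score of the lowest other I/R array (0.0485 against 0.325). A sham heart under this label, from outside the series, is consistent with the data: the array lay beyond 7 sham arrays on the I/R side for 14.9% of I/R probes, and sham arrays tested in the same way did so for 6.06% to 22.4%. A heart that did not respond to I/R cannot be told apart from a sham heart, because both predict its 3.24% of the mean response (sham arrays −15.0% to 13.5%). Neither by itself predicts the array's ILMN_2729762 value of 10.59 log2. That value lay above the other wild-type arrays (at most 8.30) and below every transgenic array (TG_Sham at least 12.05, TG_IR at least 11.14). For ILMN_1215469, the array stood at 12.22 log2, above every transgenic array (at most 11.82). RNA of a transgenic sham heart may also be present: ILMN_2729762 gave a share of 25.1% of the signal of TG_Sham replicates 1 and 2 (other wild-type arrays −0.978% to 3.13%) and 9 probes high in them a median of 17.9% (others −6.25% to 6.03%). The values leave this open, since these 9 were also higher in TG_IR replicate 2 than in the other TG_IR arrays, 6 of them belong to the set above, and ILMN_1215469, lower in transgenic hearts, gave 4.83% (others −12.9% to 27.2%), while ILMN_1241151 and ILMN_2593694, lower in TG_Sham replicates 1 and 2, gave 78.7% and 77.2% but were also lower after I/R in wild type.

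Other divisions of the arrays were counted for each comparison. For I/R in wild type, 3 of the 35 splits of the 8 arrays gave as many probes as the real 1865, so this count alone does not exclude chance. The highest other split gave 2298, with WT_Sham replicate 4 in the place of WT_IR replicate 2, and each split that gave any calls kept WT_IR replicates 1, 3 and 4 together. Calls shared with the transgenic response, which has its own sham arrays, numbered 1440 in the same direction and 1 in opposite directions. The shared estimate of spread can raise the overlap but does not set its direction. This agreement in direction argues against chance as the source of the response. The shared calls cannot favour the real grouping over the other splits that keep these WT_IR arrays together, for which the overlap was not counted. For I/R in transgenic hearts, 1 of the 35 splits, the real one, gave as many as 3860, and the highest other gave 1. No share lower than 1 of 35 was possible, and it was not adjusted for the number of comparisons examined. The count therefore argues against chance but does not exclude it. For TG against WT after sham, 1 of 35 splits gave as many as the real 4, and the highest other gave 0. The same limit holds, and the real count was as low as 2 when single arrays were left out, so this count does not exclude chance. For TG against WT after I/R, 35 of 35 splits gave at least the real 0, as any split must, so the count says nothing about chance. The highest of them, TG_IR replicates 1 and 3 with WT_IR replicates 1 and 3 against the rest, gave 225, which points to a structure of the samples. The rest held WT_IR replicate 2 and the next lowest response scores (0.325 and 0.376), and what the split reflects was not tested. For the interaction, 100 of 100 drawn assignments of genotype within each surgery gave at least the real 0, as any must, and the highest gave 1, so this too says nothing about chance. For the mean of both surgeries, 1 of 100, the real one, gave as many as 2, and the highest other gave 1. With counts this close and no adjustment for the number of comparisons, this count does not exclude chance. It does not weigh the size of the 2 differences. For ILMN_2729762, every transgenic array (at least 11.14 log2) lay above every wild-type array (at most 10.59). For ILMN_1215469, every transgenic array (at most 11.82) lay below every wild-type array (at least 12.01). Both probes were chosen on these arrays.

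ILMN_2759365, named for the largest rise among wild-type calls without overlap, stood at 9.68 log2 on the array labelled WT_IR replicate 2, above the highest sham array at 8.14. The rule required it to lie above the wild-type sham arrays but not above the transgenic ones. Over the probes with an averaged I/R change of more than 2-fold (338 to 381, depending on the sham array left out), that array lay at the I/R level for 1 to 4, and the sham arrays for 0 to 15.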
